A study of Bemisia tabaci with 2 samples.

How the data were processed

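Transcript tags were counted in 2 libraries of whole adult female whiteflies (Bemisia tabaci, B biotype), 1 from insects carrying Tomato yellow leaf curl China virus and 1 from insects without it. Per the labels' protocols, poly(A) RNA was captured on oligo(dT) beads, the cDNA was cut with NlaIII (recognition site CATG) and the fragment next to the bead was kept. The enzyme MmeI, bound at an adapter joined to the CATG end, then cut 17 bases downstream, so that each transcript gave a tag of 21 bases counting the CATG. A second adapter was joined to the MmeI end and the product was amplified by PCR. From general knowledge of the enzyme, MmeI leaves an overhang of 2 bases at its cut, which are the last 2 bases of the tag.

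The deposited files hold, per the file headers, each distinct read and its copy number, which was a whole-number count in both. All deposited reads were 35 bases long, with 17 bases of tag followed by the same 18 adapter bases; whether reads without that adapter start had been removed is not given in the sources used here. Base calling, any further read filter and the software used by the authors are not given in the sources used here. The labels' protocols describe no molecular identifiers, so copies of one molecule made by PCR cannot be told from separate molecules.

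The first 17 bases of each read were taken as the tag, written without its CATG, and positions were counted from 1 at the first base after CATG. Reads whose tag held an N were left out; they made up 0.217% of the viruliferous and 0.232% of the non-viruliferous reads. This left 3573904 and 3657051 counts. Counts were scaled to tags per 1000000 of these totals (TPM), at which 1 count was worth 0.280 and 0.273 TPM, and the limit that a count of 0 allows (3 counts in a library) was 0.839 and 0.820 TPM. Folds against a library with a count of 0 were computed against that limit and are lower bounds. Log2 ratios are of viruliferous over non-viruliferous, with a pseudocount of 0.5 added to each count.

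With 1 library per group there is no replicate and no test between conditions. The difference between the libraries was described with exact 99% Clopper-Pearson intervals of the ratio, conditional on the summed count of a tag. A tag was called higher or lower when it differed by at least 2-fold and its interval excluded a ratio of 1. Shares of reads or tags carry exact 95% Clopper-Pearson intervals. All of these intervals cover counting error only and compare these 2 libraries, not the conditions. Counts were simulated for this comparison from the real levels of 25312 tags. Changes were planted only in tags expected to have at least 100 counts in the non-viruliferous library. All 100 tags planted with a 4-fold change were called, and 53.0% of the 100 planted with a change of exactly 2-fold. Of unchanged tags, 0.43% were called. A further simulation added a shift per end class, the same for every tag of a class. Removing class medians recovered those shifts within 0.02 (log2), and 0.36% of unchanged tags were then called. The simulated counts varied by counting error only. Among real tags of at least 100 counts, the interquartile range after removing class medians was 1.34, against 0.32 expected from counting alone. The rates for planted changes therefore do not describe rarer tags, and no rate covers real variation within a class.

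Tags were not matched to genes: the identifiers of 14920 genes were at hand, but no transcript or genome sequence was used here. Comparisons planned per gene (2-fold changes per gene, the 37 gene lists, tag sites within genes and antisense tags) were therefore not made, and the comparison was made per tag, as planned for that case. The rule for named items was fixed before the data were examined, mostly for genes, and its parts that could be carried over to tags were used: the 5 tags with most counts (written for genes) and the 5 with the highest and 5 with the lowest ratio among called tags of at least 100 counts (written for tags that match no gene). Its parts for genes with product names and members of the gene lists named no tag. After the data were seen, the same choice of 5 per direction was repeated on ratios corrected for the end class, among the 50 most abundant tags, and in 8 end classes.

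End classes are the 16 possible pairs of last bases. Class scaling subtracted the median log2 ratio of a tag's class, over tags of at least 100 counts. It takes each class to have no net change of its own and was added after the data were seen. Variance explained is the share of the variance of the log2 ratio across tags between the groups formed by a base or pair of bases; tags are not replicates. Library-specific sequences were assembled from words of 8 bases found in unequal numbers of tags (of at least 5 copies) in the 2 libraries. A tag was taken to hold one when it shared a word of 8 bases with it, and to hold adapter sequence when it shared 10 bases with either adapter on either strand. Poly(A) tags held 8 or more A in a row. Alternatives were TMM scaling (edgeR), median-of-ratios scaling, minimum counts, other intervals, an exact test in edgeR with a preset dispersion of 0.04, and, added later, class scaling and the removal of groups of tags. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, were used.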

Results

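Transcript tags were sequenced from adult females of the whitefly Bemisia tabaci, a sap-feeding insect that carries begomoviruses between plants. The B biotype culture was kept on cotton. Newly emerged adults fed for 24 h on tobacco infected with Tomato yellow leaf curl China virus (the viruliferous group) or on healthy tobacco (the non-viruliferous group), and then for 120 h on cotton, after which about 1000 females per group were taken for RNA. Each group was 1 library, so no difference below has a replicate check, and the intervals cover counting error only. The comparison asks how transcript levels of the insect differed with the virus. Tags are given by their 17 bases after CATG, because they were not matched to genes here.

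The viruliferous library held 3581661 reads and the non-viruliferous library 3665554. Without reads holding an N, these fell into 240042 and 260520 distinct tags, of which 63.6% (95% interval 63.4 to 63.8) and 64.0% (63.8 to 64.2) were seen once. In the viruliferous library 20.5% of the tags seen once lay 1 mismatch from a tag of at least 100 counts, against 19.0% in the other. Of 407936 distinct tags in all, 92626 (22.7%) were found in both libraries, and these held 93.5% of the viruliferous and 93.1% of the non-viruliferous counts. Of the 14404 tags with at least 20 counts in the viruliferous library, 97.3% were also found in the other; of the 15027 such tags in the non-viruliferous library, 97.1% were.

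A single tag dominated both libraries at a similar level. The tag ATCTGAGTTCAGACCGG made up 14.9% of viruliferous counts (95% interval 14.89 to 14.97) and 13.9% of non-viruliferous counts (13.87 to 13.94), a 1.07-fold difference. TAAGATTTATTTGGGCG stood at 9492 TPM in the viruliferous and 10185 TPM in the non-viruliferous library, also 1.07-fold apart. CAGACACACATCTACAG was 1.57-fold higher in the viruliferous library, with a log2 ratio of 0.65 (99% interval 0.62 to 0.68), and did not reach 2-fold. The other 2 of the 5 most abundant tags were far apart. TTTATTGGAGTAAATTT was 5.603-fold higher in the viruliferous library, at 21224 against 3788 TPM, and TTCCTCAGTTGATCAAA was 7.63-fold lower, at 2446 against 18663 TPM. Both have ends whose tags as a class were shifted the same way (described next), and relative to their classes their log2 ratios were -1.35 and -0.31, so that the direction of the first turned. The second was no longer 2-fold apart relative to its end class, but was 2-fold lower relative to tags of the same end class and similar G+C count (-1.07). The 10 most abundant tags of each library took 22.9% of its counts in the viruliferous and 22.2% in the non-viruliferous library, and the 100 most abundant took 37.2% and 37.0%.

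Over all tags, 7872 were higher and 8713 lower in the viruliferous library by at least 2-fold with an interval that excluded no change. Among the 7327 tags of at least 100 counts, 1808 were higher and 1802 lower, and the median log2 ratio was 0.05. The interquartile range of the log2 ratio in these tags was 1.94, against 0.32 expected from counting alone at their median counting error. Across them, Pearson's r between the log10 counts of the 2 libraries was 0.20; tags are not independent replicates, and the value is for tags chosen by their summed count.

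**Figure D1:**
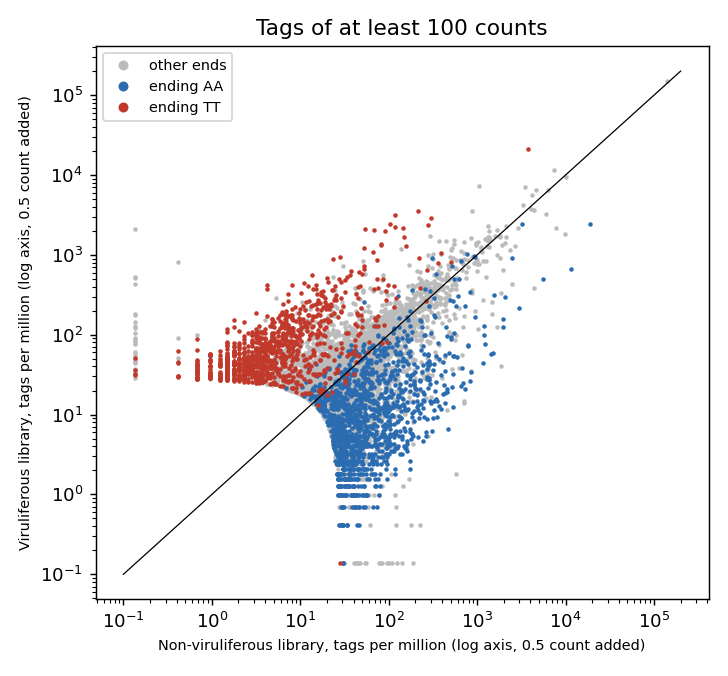
Each point is 1 of the 7327 tags of at least 100 counts, plotted by its TPM in the non-viruliferous (x) and viruliferous (y) library on log axes with 0.5 count added; the line marks equal levels. Tags ending TT lie mostly above the line, with a median log2 ratio of 3.83, and tags ending AA mostly below it, with a median of -2.62.

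The direction of a tag's difference went with its last 2 bases. Tags ending TT were higher in the viruliferous library almost throughout: of 955 with at least 100 counts, 908 were called higher and 1 lower, and their median was 14.3-fold. Tags ending AA were lower, with 1009 of 1313 called lower, 13 called higher and a median of 6.17-fold. Tags ending CT (median log2 ratio 1.73), TC (1.52) and AT (0.70) also lay on the higher side, and tags ending GA (-1.46), CA (-1.01) and CG (-0.62) on the lower side. The remaining 8 classes (AC, AG, CC, GC, GG, GT, TA and TG) had medians within 0.35 of 0. Tags ending TT made up 19.1% of all viruliferous counts (95% interval 19.0 to 19.1) and 2.31% (2.29 to 2.33) of non-viruliferous counts, and tags ending AA 5.67% (5.64 to 5.69) and 23.5% (23.5 to 23.6). Of the tags called higher among those of at least 100 counts, 84.7% ended TT, TC, CT or AT, and of those called lower 79.1% ended AA, CA or GA.

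Within the tag, the base at position 17 accounted for 39.98% of the variance of the log2 ratio and the base at position 16 for 22.6%, while no position from 1 to 15 accounted for more than 2.50%. Positions 16 and 17 as a pair accounted for 59.4%, and positions 14 and 15 for 4.90%. In the AA class the shift went with base composition: tags with at most 2 G or C had a median log2 ratio of -4.02 (362 tags) and tags with at least 7 had -1.03 (174 tags). In the GA class the corresponding medians were -2.62 (20 tags) and -0.79 (148 tags), and in the TT class 3.92 (160 tags) and 3.73 (131 tags). Poly(A) tags, which were scarcer in the viruliferous library (described next), were not left out of these medians. In the AA class, tags poor in G and C include many of them, so base composition and A runs were not separated there.

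**Figure D2:**
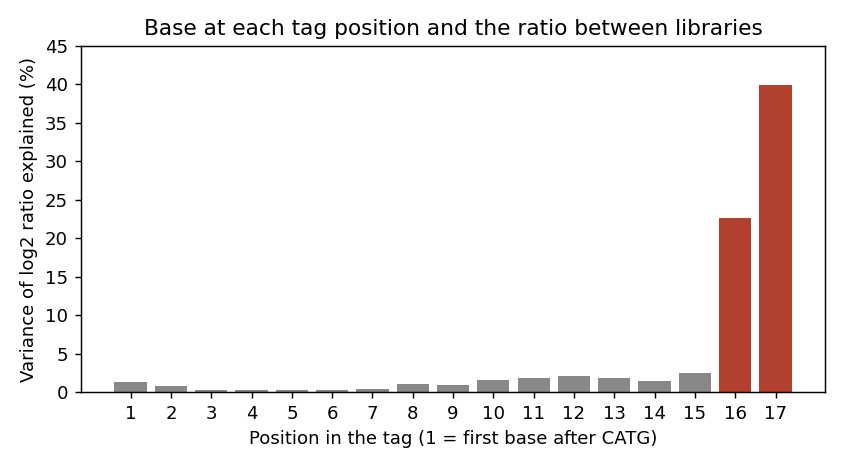
Bars give, for each tag position (x, 1 is the first base after CATG), the percent of the variance of the log2 ratio across 7327 tags that lies between the 4 bases at that position (y). Positions 16 and 17 (red) stand at 22.6% and 39.98%, all others at 2.50% or less.

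**Figure D3:**
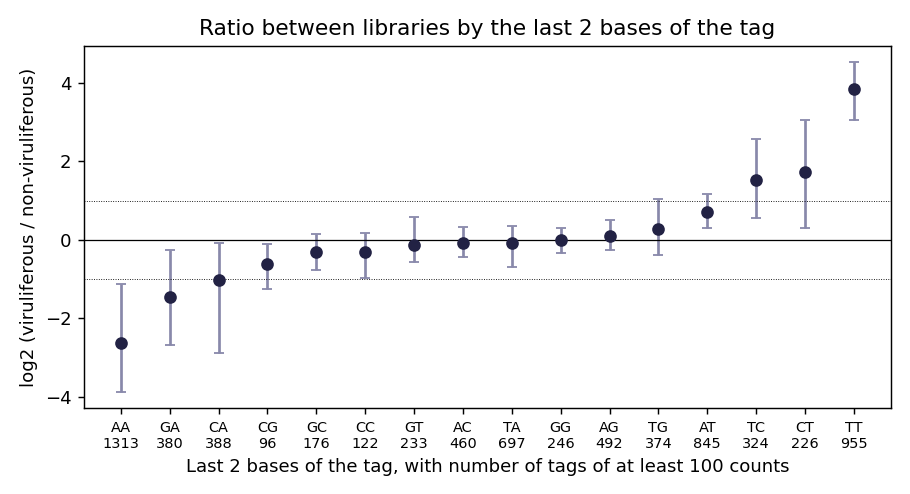
Points are the median log2 ratio of viruliferous over non-viruliferous (y) of tags of at least 100 counts in each of the 16 classes of last 2 bases (x, with the number of tags); bars span the quartiles and dotted lines mark 2-fold. Medians run from -2.62 in AA to 3.83 in TT.

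Tags with long runs of A, such as a tag reaching the poly(A) tail would hold, were scarcer in the viruliferous library. Tags with 8 or more A in a row took 0.621% of its counts (95% interval 0.613 to 0.630) and 6.27% (6.25 to 6.30) of the non-viruliferous counts. Among the tags of this kind, TAAAAAAAAAAAAAACC and GAAAAAAAAAAAAAACC were among the 5 with the lowest ratio, with 0 counts against 453 and 399, at least 148-fold and 130-fold lower. Tags holding AATAAA, the usual polyadenylation signal of animal messenger RNA, took 3.96% (3.94 to 3.98) of viruliferous and 3.27% (3.25 to 3.29) of non-viruliferous counts. Of the counts of tags with an A run, 55.6% in the viruliferous and 83.3% in the non-viruliferous library were of tags ending in A, and tags ending AA, CA or GA were lower in the viruliferous library in their class medians.

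Of the 5 tags with the highest and the 5 with the lowest ratio, most ended in part of a short sequence that was more common in the tags of the library where they were found. GGGGTTTTTACAGTCTG had 7636 counts in the viruliferous library and 0 in the non-viruliferous, at least 2605-fold higher. In the non-viruliferous library GGGGTTTTTCCAGTACT had 512 counts and in the viruliferous library 0, at least 167-fold lower there. GAAATCTTGGATCATTA (1870 against 0 counts, at least 638-fold), TAAAAGTGTCCGCACAG (1817 against 0, at least 620-fold), GTGGTTGTTCACAGTCT (1546 against 0, at least 527-fold) and GAAATCTTGGATCATAC (2898 against 1 count, log2 ratio 10.95 with a 99% interval of 8.64 to 19.17) completed the 5 highest ratios. TCGGACTGTACCAGTAC (0 against 693 counts, at least 226-fold) and TCGGACTGTAGCCAGTA (0 against 368, at least 120-fold) were the others at the low end. Tags sharing 8 bases with ACAGTCTGGAT took 3539 TPM of the viruliferous and 135 TPM of the non-viruliferous library. Tags sharing 8 bases with CCAGTACTTCTC took 544 and 1135 TPM.

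At a minimum of 20 counts in 1 library and 0 in the other, 382 tags were found only in the viruliferous and 433 only in the non-viruliferous library. Of the first, 40 held library-specific or adapter sequence, with 35.9% of their counts, and 296 of the other 342 ended TT, TC, CT or AT. Of the second, 30 held such sequence, 189 others had a poly(A) run, and 301 of the 403 without such sequence ended AA, CA or GA. At the 20-count minimum the lower bounds of these differences start at 6.82-fold and 6.52-fold.

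In the 8 end classes chosen for medians near 0, 235 of 2800 tags of at least 100 counts were higher and 308 lower, and the interquartile range of the log2 ratio was 0.91. The calls were uneven between these classes, with 97 higher and 37 lower in TG and 30 higher and 122 lower in TA. Variants of abundant tags from other end classes were kept in what follows. The tag named below at 8.39 against 102.5 TPM differs only in its last base from a far more abundant tag. That tag stood at 8742 against 68250 counts (log2 ratio -2.93), in an end class shifted the same way. The variant is therefore not shown to be free of the end-class shift. Leaving out library-specific, adapter and poly(A) tags and asking for at least 20 counts in each library, 205 tags of the 8 classes were higher and 244 lower out of 2691. The highest was GGATGTGTGTCTGAAGT, at 95.1 against 9.30 TPM (log2 ratio 3.34, 99% interval 2.70 to 4.09). GTTTTGTAATAAATTTG (78.9 against 9.84 TPM), AAAAGATTACTCTCAGT (360.1 against 50.6 TPM), GAACCCTCATAGTTTTG (42.8 against 6.29 TPM) and TGTAATTGGACCTAAGT (48.1 against 7.11 TPM) followed, from 8.02-fold to 6.77-fold higher. At the low end stood TAAAAGTGTCCGCCCAG (16.5 against 298.3 TPM), which ends in the first 4 bases of CCAGTACTTCTC, too few for the rule of 8 shared bases that removed library-specific tags, and shares its first 13 bases with the viruliferous-only tag TAAAAGTGTCCGCACAG. ATACCCTACAGAAATTA (10.4 against 147.1 TPM, log2 ratio -3.81, 99% interval -4.52 to -3.21), TTCCTCAGTTGATCAAC (8.39 against 102.5 TPM), AAGTAATGTCTCACTTA (6.16 against 61.8 TPM) and TGCAATTAAGTAAATTA (12.6 against 118.9 TPM) were the others.

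Relative to the median of their end class, 4270 tags were higher and 4850 lower, and 4310 of the 16585 tags called on unscaled counts were called in the same direction. Another 442 were called in the opposite direction. After leaving out library-specific, adapter and poly(A) tags, the 5 highest class-scaled ratios belonged to GAAATCTTGGATCATTA, TAAAAGTGTCCGCACAG and GAAATCTTGGATCATAC, named before, and to ATTGTTAAATTTTTACA (649 against 0 counts, at least 221-fold unscaled) and GCCTCGTGGTTAAGACA (324 against 0, at least 111-fold). The 5 lowest were TGAGCACATGTATCCAG (1 against 836 counts), AGTACTATCAGCCAGTA (0 against 200), CTATGTTTTGTCCAGTA (0 against 199), ACAATGTCAATGTATCC (1 against 447) and TGAGCACATGTACCAGT (0 against 114). Of these 10 tags, all but GAAATCTTGGATCATTA end in at least 2 bases of the sequence of the library in which they were found.

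Among the 50 most abundant tags, 8 were higher and 11 lower on unscaled counts, and 8 and 9 relative to their end class. The lowest relative to class were TAAAGTGTTAGGCCATC, at 1155 against 2348 TPM (log2 ratio -1.02, class-scaled -2.55), and ACTCAATTCTTGATTCA, at 381 against 4394 TPM (-3.53 and -2.51). CGCAAGTGATCTACACC stood at 427 against 2494 TPM (-2.55 and -2.24), in a class with a median near 0. TTCCTCAGTTGATCATA stood at 2157 against 7764 TPM (-1.85 and -1.76), and GAACCCAGTTAAAATAA at 674 against 11408 TPM (-4.08 and -1.46). The highest relative to class were AGCTTGAAGGACCCCAA (2419 against 3244 TPM, class-scaled 2.20), GGATATGCTCGGCAGGA (6541 against 4628 TPM, 1.96), GGCTTCGCACTGTTTGA (4176 against 3335 TPM, 1.78), GGCTTCGGTCTCTTTGA (2074 against 1698 TPM, 1.75) and CACCAGAAACAGAAAGA (1723 against 1746 TPM, 1.44). On unscaled counts none of these last 5 was 2-fold apart, AGCTTGAAGGACCCCAA lay below 0 and the interval of CACCAGAAACAGAAAGA included 0, and all 5 are tags with at least 7 G or C in the AA and GA classes. Relative to tags of the same end class and similar G+C count, their log2 ratios were smaller: 0.61 for AGCTTGAAGGACCCCAA and 0.77 for CACCAGAAACAGAAAGA, both short of 2-fold, and 1.29, 1.11 and 1.08 for the others in the order named.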

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

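The count of 16585 tags at least 2-fold apart (47.5% of them higher in the viruliferous library) stayed within 1.5 times under TMM (16746) and median-of-ratios scaling (16737), which both raised all ratios by 0.03 on the log2 scale, and with tags seen at least 2 times (17848), a 95% interval (22643) or an assumed biological coefficient of variation of 0.2 in edgeR (13359). It fell to 8092 when the interval had to lie wholly beyond 2-fold and to 3610 among the fewer tags of at least 100 counts. Of the alternatives chosen after seeing the data, class scaling gave 9120 calls (46.8% higher), class and G+C scaling 8420 (41.8% higher), and the 8 end classes with medians near 0 alone 2376 (36.7% higher, from 163098 tags). Tags without library-specific or adapter sequence (16419), without poly(A) runs (15108), summed over the last 2 bases (15988), without the most abundant tag (16734) or with tags holding an N (16615) stayed within 1.5 times. The 815 tags found in 1 library only became 159 at a minimum of 50 counts, and 745 and 681 without library-specific or adapter tags and as tags of 15 bases. The share of distinct tags found in both libraries was 22.7%, and 40.2% among tags seen at least 2 times in a library. Of the 42 named tags, TTTATTGGAGTAAATTT changed direction under class scaling (-1.35) and under class and G+C scaling (-1.38), and AGCTTGAAGGACCCCAA did too (2.20 and 0.61, from -0.42), the second value short of 2-fold. TAAGATTTATTTGGGCG turned from -0.10 to 0.52 and 0.63, in each case short of 2-fold. CACCAGAAACAGAAAGA, near 0 at -0.02, was above 0 under every other scaling (1.44 with class, 0.77 with class and G+C scaling). Both scalings subtract a median of the tag's class, so these shifts follow from their construction. TAAAGTGTTAGGCCATC fell just under 2-fold with TMM and with median-of-ratios scaling (-0.99). Other ways of matching tags to genes and of scaling to matched tags were not run because tags were not matched to genes. No paired analysis was possible because each group has 1 library, and no replicate could be left out. Depth limits the comparison of rare tags, since a count of 0 allows up to 0.839 TPM in the viruliferous and 0.820 TPM in the non-viruliferous library.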

Other observations

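The tests of the positions of the last 2 bases, of mirror tags, of the tags left with neither feature, of the end classes of far-apart tags, of G+C trends within classes and of the ribosomal RNA primer were chosen after their results were seen, as was the choice of the tag group described first; those of substituted bases, of the number of far-apart tags in each library, of G+C content over all classes and of the spread in classes with medians near 0 were set out before. Tags sharing the first 15 bases TTCCTCAGTTGATCA formed the second most abundant group in the non-viruliferous library, at 36513 TPM against 6460 TPM in the viruliferous (log2 ratio -2.50). Unlike most 15-base groups, whose leading variant held a median of 99.3% of counts, this one had 3 common ends. Its variants ending AA, GA and TA (TTCCTCAGTTGATCAAA, TTCCTCAGTTGATCAGA and TTCCTCAGTTGATCATA) took 37.9%, 27.98% and 33.4% of it in the viruliferous library and 51.1%, 26.9% and 21.3% in the non-viruliferous. Relative to their end classes they stood at -0.31, -0.98 and -1.76, but scaling by class and G+C count gave -1.07 for the AA variant and -1.71 for the TA variant, so the size of the contrast between these variants depends on the scaling.

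The most abundant tag may come from the mitochondrial large-subunit ribosomal RNA. All 17 bases of ATCTGAGTTCAGACCGG match the reverse complement of CCGGTCTGAACTCAGATCACGT, a general animal primer for that RNA written down from general knowledge. In that reverse complement these bases follow CGTG, whereas every tag follows CATG. The match therefore breaks at a single base within the recognition site. Among the 1000 most abundant tags, leaving out variants of this one within 2 substitutions, the next best matched at 11 of 17 bases. The tag was not matched to the whitefly's own mitochondrial sequence, so this is a hypothesis.

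The ratio between the libraries followed the last 2 bases of the tag, which explained 59.4% of its variance across tags, against at most 4.92% for any neighbouring pair within positions 1 to 15. A transcript response to the virus as the whole cause is argued against by the 4.90% at positions 14 and 15, since the place where MmeI cuts has no meaning for a transcript. Substituted last bases are argued against too: after summing each tag with its variants at the last 2 bases, the end of the leading variant still explained 62.3%. A step acting on the MmeI end, such as the joining of the second adapter to the overhang of 2 bases, is consistent with all 3 values and is the candidate explanation. A read filter applied before deposit that depended on these bases was not tested and stays open.

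Of the 215 tags of at least 100 counts that were over 32-fold apart and had no poly(A) run, 169 were higher in the viruliferous library and 46 in the other. The first number was 3.67 times the second, which by itself leaves viral transcripts undecided. In 48 of them the tag ended in at least 2 bases of its library's own sequence, and 97.9% of these had a mirror tag, the same upstream bases before the other library's sequence. Of 541 other tags, chosen by their last 2 bases, 12.01% had one. Most of the 48 ended in more than 2 bases of the sequence, and some mirror tags had few counts. The 2 sets were therefore not matched, and the contrast between their shares decides nothing. Where a tag ended in 5 or fewer bases of the sequence, its mirror tag differed from it at 1 base only. Such a mirror tag cannot be told from a 1-mismatch neighbour. The mirror tags of longer ends fit an oligonucleotide of each library's own joined to short fragments. The sequence CCAGTACTTCTC was not exclusive to the non-viruliferous library, since tags sharing 8 bases with it took 544 TPM of the viruliferous and 1135 TPM of the non-viruliferous library, and the source of the former was not tested. Viral transcripts are argued against for these, because 96.8% of those higher in the viruliferous library had their mirror tag in the virus-free library (GAAATCTTGGATCATAC with 2898 counts and GAAATCTTGGATCATCC with 692, for example). This argument holds only for tags ending in more than 5 bases of the sequence. The example just given ended in 2, and for such short ends the share cannot decide on viral transcripts. Of the 168 tags without a mirror tag, 160 (95.2%) ended in the shifted end classes of their direction, but those classes were defined by the same ratios, so this share decides nothing about the cause, and viral transcripts stay open for the 139 of the 168 that were higher in the viruliferous library.

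The 8 tags with neither a mirror tag nor an end in the shifted classes just named were singled out after their values were seen. They were too few to decide on viral transcripts, with 5 higher in the viruliferous and 3 in the non-viruliferous library (1.67 times, 95% interval 0.324 to 10.7). The interval takes the tags as independent, which variants of other tags may not be, and it measures no spread between conditions. Higher in the viruliferous library were AGTCAGTCTTGGCATAA, AGTTAAAATTCTTTTAC, ATCTGAGTTCAGACTGT, GAAATCTTGGATCATTA and GGGGTTTTTACAGCCTG, and higher in the other were ACCGATCAATCCAATTA, ATGGACTGCTCAGCACG and TACCAAGTGAAATGGGC. Of the first 5, 4 lay within 2 mismatches of another tag of at least 100 counts, and of the other 3, 2 did. In the order listed, tag 3 of the first 5 lay 2 mismatches from the most abundant tag of both libraries. Tag 4 lay 2 mismatches from both tags of the mirror pair with 2898 and 692 counts given above. At 1 mismatch, GGGGTTTTTACAGCCTG had GGGGTTTTTACAGTCTG, which ends in the library's own sequence. The nearest neighbours of AGTCAGTCTTGGCATAA, ATCTGAGTTCAGACTGT and GAAATCTTGGATCATTA, also at 1 mismatch, were found in both libraries: in that order, AGTCAGTCTTGGCATAC and AGTCAGTCTTGGCATAG, ATCTGAGTTCAGACCGT and ATCTGAGTTCAGACTGG, and GAAATCTTGGATCATTC (385 and 129 counts).

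In the 8 end classes chosen for medians near 0, without tags recognized as library-specific, adapter or poly(A), 227 of 2740 tags were higher and 271 lower in the viruliferous library. Their G+C count explained 0.390% of the variance of the log2 ratio over all classes, and separate linear trends in each class 1.72%, which argues against base composition as the cause of most of the spread. In the TG class alone the trend explained 6.94%. The end pair explained 4.07% and the base at position 2 explained 4.13%. The interquartile range of 0.89 exceeded the 0.28 expected from counting, but with 1 library per group a response to the virus cannot be told apart from a difference between the insect samples or between library preparations.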
